A study of Homo sapiens with 16 samples.

How the data were processed

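Gene expression was measured in A172 cells, an established human glioblastoma cell line, on Affymetrix Human Genome U133 arrays (A version 2.0). The 16 arrays fall into 8 groups of 2, each pair labelled as biological replicates. Erstressin and nostressin, the 2 compounds of the series, were each applied at 10 µM in 0.1% DMSO and sampled at 30 min, 6.5 h and 18 h. Erstressin was also sampled at 18 h without cytokines, and vehicle was sampled at 6.5 h. Per the labels' protocols, cells stood 18 h in culture with 10% serum before stimulation with a cocktail of IFN-γ (4000 U/ml), TNF-α (40 ng/ml) and IL-1β (4 ng/ml). The labels do not state whether the vehicle cultures received the cocktail, so vehicle is named here without that detail. Total RNA was purified with on-column DNase digestion and checked on a Bioanalyzer, and 5 µg per sample was analysed, per the labels' protocols.

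The authors deposited 1 table of 22277 probe sets. GCRMA, a background correction and summary method for Affymetrix arrays, is the tool named in the submitters' processing notes, and its version is not given in the sources used here. The deposited values are not log2 GCRMA signals. Each is a linear ratio of a probe set's value to a centre that the authors set for that probe set, with a floor of 0.01 and a highest value of 109.6. The centre fits a median over 18 arrays, 2 of them not analysed here. A median over all but 2 of the 16 arrays could give the same ranks, so the ranks do not tell these apart. In 62.0% of probe sets the mean of the values ranked 7 and 8 equals 1 within 2e-06, and in 23.3% that of ranks 9 and 10, against 3.40% for ranks 8 and 9, the middle of the 16 arrays. Array medians of the ratio lay between 0.987 and 1.01. Because the ratios carry no expression level, no gene can be called detected or undetected, and the fold of a gene near background may be understated. The floor holds 40 values of 7 probe sets, all in the 30 min and unstimulated arrays. They belong to CCL5, CXCL10, GBP1, VCAM1 and a probe set without a single symbol. Folds of these 4 genes against those groups are lower bounds, computed per probe set against the floor. No table column was left unused (0).

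The design fixed before the data were examined expected log2 signals, and 2 of its rules could not be applied to centred ratios. Values under 1 were not set to 1, and the probe set with the highest mean could not stand for a gene, because a high mean of centred ratios is not a high signal. That choice was kept only as an alternative. The log2 ratio was therefore used as it stands, with the mean of all probe sets of a gene. No filter on low values was applied, as the design foresaw for centred values. Of all probe sets, 19064 carried a single gene symbol, 1043 several, 2108 none and 62 were controls. The single-symbol probe sets gave 11963 genes, 7653 of them from 1 probe set and 4310 from several. Gene identifiers matched the current gene table for 19052 of these probe sets and led to 0 changes of symbol. Exactly 1 probe set moved against the direction of its gene in 4 of the calls for named genes, on FN1, TNC and RPS6. Calls with more than 1 opposing probe set were not counted. No genome build was named, so no coordinates are given.

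Genes were tested with limma 3.58.1 in R 4.3.3, with 1 model over all 16 arrays and a mean per group. Benjamini-Hochberg adjustment was over the 11963 genes at 0.05. The variance prior had what limma treats as an intensity trend. Here that trend follows a gene's mean centred log2 ratio, so it does not adjust for signal level. Tests were 2-sided. The model left 8 residual degrees of freedom and a prior of 5.11. The median standard error of a difference was 0.115 on the log2 scale, and the median 95% confidence interval reached 0.248 to each side. With 2 arrays per group, the number of arrays limits the precision. There are 6 main comparisons, 4 comparisons of times within a compound, and 2 tests of whether the change over time differed between the compounds. The p-values measure the spread between replicate cultures only, pooled over all 8 groups and drawn towards the prior. A gene therefore has the same SE in each comparison of 2 groups, even where its spread differs between groups. NOS2, for example, had an SD of 0.57 on the log2 scale under erstressin and 0.025 under nostressin at 6.5 h. The labels do not say whether replicate cultures were grown on separate days.

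Gene lists were tested with camera from limma, at a preset correlation of 0.01, over 21 lists in 6 comparisons (126 tests, adjusted together). Of 534 list members, 466 were tested. The lists cover ER chaperones and folding enzymes, ER-associated degradation, ER translocation and vesicle traffic, the integrated stress response, amino acid synthesis and transport, aminoacyl-tRNA synthetases, NF-kB targets, cytokines and chemokines, antigen presentation, oxidative stress, cytosolic heat shock, immediate early genes, sterol and fatty acid synthesis, DNA replication, mitosis, p53 targets, hypoxia and glycolysis, extracellular matrix, metallothioneins and ribosomal proteins, and 1 more that is not reported here. Of the 67 calls at the preset correlation, 13 held when the correlation was estimated from the data. Among them are ER chaperones and amino acid synthesis in the 3 comparisons of erstressin with vehicle or nostressin at 6.5 h and 18 h, the integrated stress response in both of those at 6.5 h, cytokines and chemokines between the compounds at 18 h, and the antigen presentation, NF-kB and cytokine lists between stimulated and unstimulated erstressin cultures. A further 4 lists held markers of leukocytes, epithelial cells, endothelial cells and glia or mesenchymal-type glioma.

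Genes are named in the text by a rule. A panel of 20 genes is followed in each main comparison. Each main comparison adds the 6 largest rises and 6 largest falls among genes past the test with both arrays of a group above both of the other. It also adds the 3 passing members of largest fold from each list with at least 3 such members, and each test of time adds the 4 largest rises and 4 largest falls. In the 10 comparisons of 2 groups, 385 of 470 named values passed the test, a share that the rule itself largely sets. The code was tested on simulated data with 200 genes changed, drawn once per comparison. Only the mean and fitted spread of each gene came from the real arrays. The noise was normal, independent between genes and equal in all groups, so correlated genes and unequal spreads were not covered. In the simulation of erstressin against vehicle at 6.5 h the code recovered 56.7% of genes changed by 0.5 on the log2 scale, 98.5% at 1 and 100% at 2. It called 13 unchanged genes. The lowest recovery among the 6 simulated comparisons was 50.7% at 0.5 and 91.0% at 1. Alternatives covered scaling, the choice of probe set, the variance prior, the arrays in the model, a replicate block, and each array left out in turn. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.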

Results

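A172 glioblastoma cells were exposed to erstressin, to nostressin or to vehicle, and mRNA was profiled on 16 arrays in 8 groups of 2. The series set out to follow the effect of erstressin over time in cells stimulated with IFN-γ, TNF-α and IL-1β, with the unfolded protein response and inducible nitric oxide synthase (NOS2) among the points of interest. Values are log2 fold changes between groups ± SE with n = 2 arrays per group, and adjusted p-values are from limma unless stated. The log2 ratios of replicate arrays correlated across genes (which are not independent replicates) between 0.767 for erstressin at 6.5 h, where 32 genes lay at least 2-fold apart, and 0.954 for unstimulated erstressin. The array number of erstressin 6.5 h replicate 2 is out of sequence with the others, per the labels, and they do not say whether it was hybridized apart. The log2 ratio of the actin 3′ probe set minus that of the 5′ probe set was compared between groups as a sign of RNA integrity. Each probe set is centred on its own value, so a difference near 0 does not show intact RNA, and only differences between groups can be read. At 6.5 h it was 0.07 ± 0.33 (SD, n = 2) under erstressin and -0.10 ± 0.06 under nostressin. At 18 h it was 0.08 ± 0.08 under erstressin and -0.10 ± 0.04 under nostressin, at 30 min -0.32 ± 0.07 and -0.20 ± 0.07, in unstimulated erstressin cultures 0.15 ± 0.06 and in vehicle -0.17 ± 0.05. The same measure for GAPDH at 18 h was 0.052 ± 0.004 under erstressin and -0.094 ± 0.030 under nostressin.

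The first comparison asked which transcripts differed between erstressin and vehicle at 6.5 h. Genes of the endoplasmic reticulum (ER) stress response were higher with erstressin. DNAJB9, an ER co-chaperone, rose by 5.25 ± 0.16, DDIT3, which encodes the transcription factor CHOP, by 4.27 ± 0.16, TRIB3 by 4.12 ± 0.21, and HERPUD1, an ER membrane protein of the degradation pathway, by 3.41 ± 0.11. HSPA5, the ER chaperone BiP, rose by 1.76 ± 0.09 (adjusted p = 3.4e-08). Among the genes of inflammation, the chemokine CCL8 changed by -4.65 ± 0.18, IL1B by -2.49 ± 0.18, TNF by -2.15 ± 0.20 and NOS2 by -1.78 ± 0.21 (adjusted p = 5.8e-05). IL6 fell by 1.31 on the log2 scale (SE 0.18), CXCL10 by 0.81 (SE 0.10) and CCL2 by 0.48 (SE 0.09). ICAM1, an adhesion molecule, rose by 1.10 ± 0.20 (0.60 after quantile normalization), a call lost with only these 2 groups in the model (adjusted p = 0.057).

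Among ER chaperones and folding enzymes, 18 of 23 measured genes rose with erstressin against vehicle, 0 fell and 5 did not pass. The count was 19 rising when adjusted over the list alone, and the list's median was 0.77 (camera adjusted p = 4.7e-19). Examples are DNAJB9, SDF2L1 (2.90 ± 0.12) and MANF (2.38 ± 0.08). Of the integrated stress response list 15 of 21 rose and 0 fell (17 rising adjusted over the list alone, median 0.99, adjusted p = 5.9e-16), among them DDIT3, TRIB3 and ATF3 (1.71 ± 0.10). In the amino acid list 14 of 19 rose and 0 fell (16 rising and 1 falling adjusted over the list alone, median 1.35, adjusted p = 2.1e-18). SLC7A11, the cystine transporter, rose by 2.38 ± 0.12 and ASNS, asparagine synthetase, by 2.08 ± 0.09. Aminoacyl-tRNA synthetases had 9 of 15 rising and 0 falling (9 and 1 adjusted over the list alone, adjusted p = 9.3e-06), with GARS1 at 1.64 ± 0.13 and AARS1 at 1.23 ± 0.08. That list had an adjusted p = 0.063 with an estimated correlation. Of 24 genes of ER translocation and vesicle traffic 8 rose and 0 fell, and 12 rose adjusted over the list alone (adjusted p = 2.5e-05, adjusted p = 0.36 with an estimated correlation). In ER-associated degradation 6 of 17 rose and 1 fell (7 and 1 adjusted over the list alone), with an adjusted p = 5.8e-04 and an adjusted p = 0.36 with an estimated correlation.

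Immediate early genes had 12 of 26 members rising with erstressin against vehicle and 2 falling (13 and 2 adjusted over the list alone). MYC rose by 2.24 ± 0.17 and KLF4 by 2.20 ± 0.16. The list passed at the preset correlation (adjusted p = 4.5e-04) and had an adjusted p = 0.071 with an estimated correlation. Of 26 cytokines and chemokines 8 fell and 4 rose (9 and 4 adjusted over the list alone, adjusted p = 0.0051, adjusted p = 0.36 with an estimated correlation). IDO1, which degrades tryptophan, fell by 2.37 on the log2 scale (SE 0.14) and CXCL11 by 2.06 (SE 0.15). In the hypoxia and glycolysis list 8 of 23 fell and 1 rose (11 and 2 adjusted over the list alone, adjusted p = 0.0072, adjusted p = 0.52 with an estimated correlation). PFKFB3, a regulator of glycolysis, fell by 1.48 (SE 0.21). The p53 targets had 5 of 17 rising and 0 falling (8 rising adjusted over the list alone, adjusted p = 0.0019, adjusted p = 0.36 with an estimated correlation), with the DNA repair gene XPC at 1.12 ± 0.10. NF-kB targets had 12 of 25 rising and 2 falling (13 and 2 adjusted over the list alone, adjusted p = 6.6e-04, adjusted p = 0.33 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.85). DNA replication had 7 of 28 rising and 2 falling, mitosis 5 of 28 and 1, and extracellular matrix 3 of 29 and 0. These lists passed as higher (camera adjusted p = 0.034, 0.025 and 0.022), but not with an estimated correlation (adjusted p = 0.56, 0.69 and 0.52). Their calls were lost without vehicle replicate 1.

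In all, 1864 of 11963 genes differed between erstressin and vehicle at 6.5 h, with 1259 higher and 605 lower, and 267 and 43 of these by at least 2-fold. The count was 945 without vehicle replicate 1 (676 higher and 269 lower) and 1165 with only these 2 groups in the model (902 higher and 263 lower). The falls also moved to 380 without vehicle replicate 2 and to 1038 after quantile normalization, beside 994 and 1558 rises. PTGS2 (-0.09 ± 0.08), HMOX1 (-0.07 ± 0.10) and NFKBIA (0.06 ± 0.18) did not pass the test.

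Nostressin, the second compound, was compared with vehicle at the same time and concentration. ADM, the gene of the peptide adrenomedullin, was lower by 1.43 on the log2 scale (log2 fold change -1.43 ± 0.12, adjusted p = 3.7e-04, and -2.28 after quantile normalization), and HILPDA, a lipid droplet protein, changed by -1.03 ± 0.14. ADM was also lower with erstressin against the same vehicle arrays (-1.75, and -3.01 after quantile normalization), so its fall is not particular to nostressin. With nostressin, neither the ER stress panel nor NOS2 passed the test. The value of HSPA5 was 0.35 (95% CI 0.15 to 0.55, adjusted p = 0.11), that of DDIT3 -0.18 (95% CI -0.52 to 0.16), that of DNAJB9 0.47 (95% CI 0.12 to 0.82) and that of NOS2 0.52 (95% CI 0.07 to 0.97, adjusted p = 0.32). In total 57 genes passed, 45 higher and 12 lower, against 1386 at an unadjusted p under 0.05. The count dropped to 1 gene, ADM, without nostressin replicate 1, nostressin replicate 2 or vehicle replicate 1, and to 29 without vehicle replicate 2. It was 378 after quantile normalization (277 higher and 101 lower) and 372 with only these 2 groups in the model (283 higher and 89 lower). Testing all probe sets gave 90. The call for HILPDA was lost without nostressin replicate 1 (-1.02), nostressin replicate 2 (-1.04) or vehicle replicate 1 (-1.13).

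Neither ER chaperones nor the integrated stress response passed for nostressin against vehicle. ER chaperones had 1 gene rising and 1 falling of 23 (4 and 2 adjusted over the list alone, median 0.09, adjusted p = 0.71), and the integrated stress response had 0 of 21 passing (2 rising adjusted over the list alone, median 0.05, adjusted p = 0.39). The hypoxia and glycolysis list was lower (median -0.19, camera adjusted p = 7.5e-10, adjusted p = 0.13 with an estimated correlation), although only ADM fell of its 23 members when adjusted over all genes. Adjusted over the list alone, 7 fell and 1 rose. Metallothioneins had a median of -0.19 with 0 of 8 members passing and 1 falling adjusted over the list alone (adjusted p = 4.8e-04, adjusted p = 0.36 with an estimated correlation), and the median was -0.12 without vehicle replicate 1. NF-kB targets had a median of 0.18 with 0 of 25 passing and 5 rising adjusted over the list alone (adjusted p = 3.0e-04, adjusted p = 0.30 with an estimated correlation), a call lost after quantile normalization (median 0.05, adjusted p = 0.16). Aminoacyl-tRNA synthetases had 1 of 15 rising and 0 falling (4 rising adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.36 with an estimated correlation), a call lost without nostressin replicate 1 (adjusted p = 0.061), after quantile normalization (adjusted p = 0.080) and with the probe set of highest SD (adjusted p = 0.053). Sterol and fatty acid genes had 0 of 20 passing (2 rising and 1 falling adjusted over the list alone, adjusted p = 0.015, adjusted p = 0.44 with an estimated correlation), a call lost without nostressin replicate 1 (adjusted p = 0.052) or vehicle replicate 1 (adjusted p = 0.12), after quantile normalization (adjusted p = 0.052) and with the probe set of highest mean (adjusted p = 0.81). Extracellular matrix genes had 0 of 29 passing (3 rising adjusted over the list alone, adjusted p = 0.0062, adjusted p = 0.47 with an estimated correlation), a call lost without nostressin replicate 1 (adjusted p = 0.052).

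At 30 min the compounds were compared in cells just stimulated. No gene passed (0 of 11963 with limma), 249 genes or 2.08% had an unadjusted p under 0.05, and 1 gene, C1D (chosen after its value was seen), passed after quantile normalization (-0.93, adjusted p = 0.038). NOS2 differed by 0.10 (95% CI -0.35 to 0.55), HSPA5 by -0.12 (95% CI -0.32 to 0.08) and DDIT3 by 0.17 (95% CI -0.17 to 0.51). The stress transcription factor ATF3 differed by 0.44 (95% CI 0.21 to 0.66, adjusted p = 1). CXCL10 lay at the floor of the deposited values in all 4 arrays, so no fold is given. The integrated stress response list was shifted up by a median of 0.12 (adjusted p = 3.7e-04, adjusted p = 0.13 with an estimated correlation) with 0 of 21 members passing and 1 passing adjusted over the list alone. That shift was lost without nostressin 30 min replicate 2 (median 0.05, adjusted p = 0.16). Cytokines and chemokines were shifted up by a median of 0.07 with 0 of 26 members passing, also 0 adjusted over the list alone (adjusted p = 0.019, adjusted p = 0.41 with an estimated correlation). That call was lost without erstressin 30 min replicate 2 (adjusted p = 0.16), without nostressin 30 min replicate 1 (adjusted p = 0.87), after quantile normalization (adjusted p = 0.27), and with the probe set of highest SD (adjusted p = 0.085) or highest mean (adjusted p = 0.074). The median was 0.04 without erstressin 30 min replicate 1 and 0.11 without nostressin 30 min replicate 2.

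**Figure D1:**
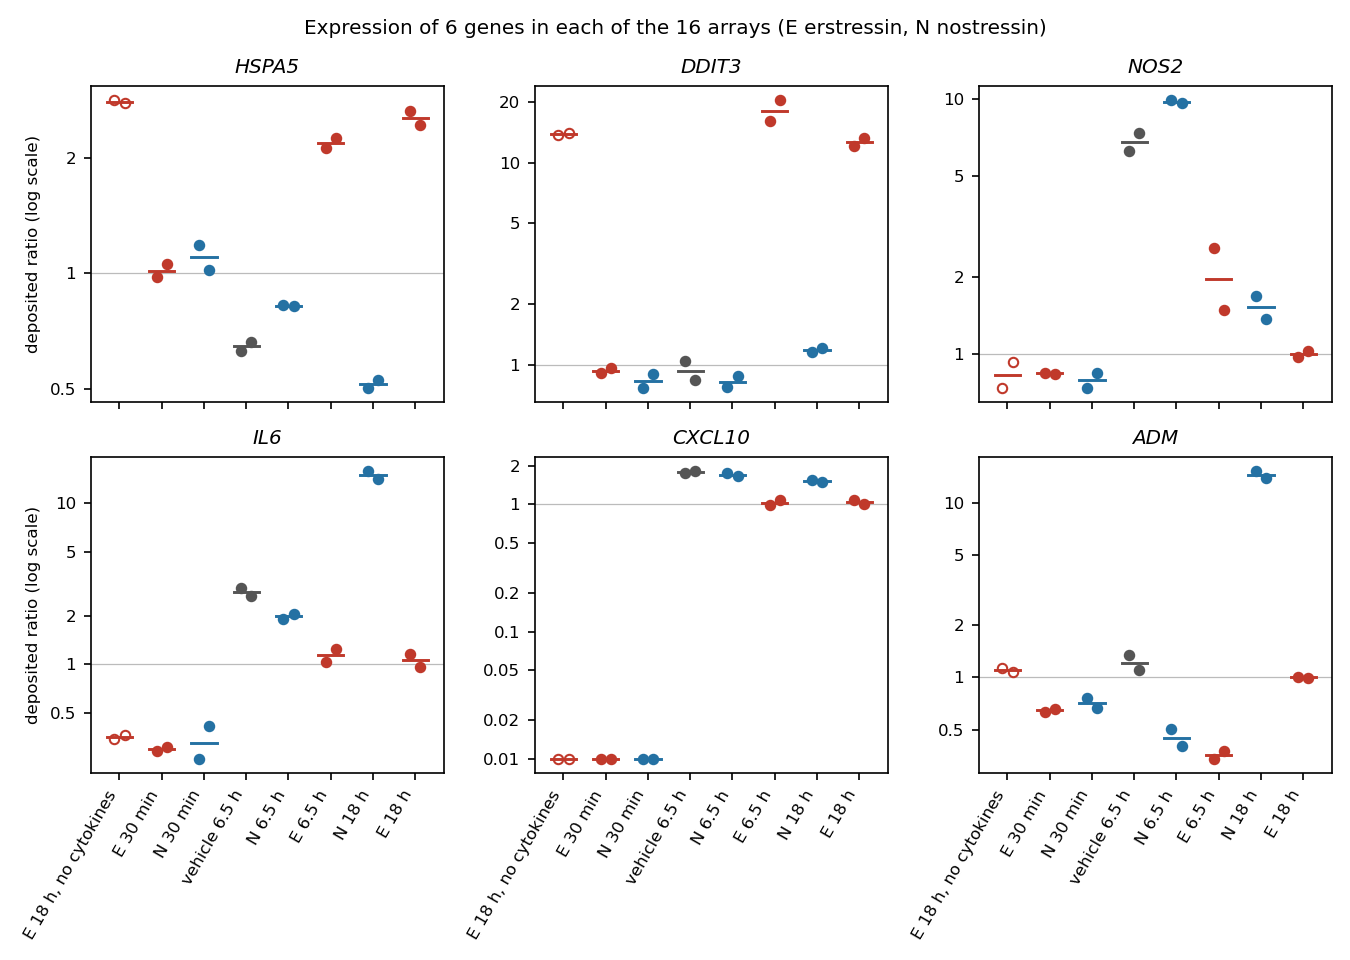
Deposited ratio (log scale) of 6 genes in each array, with a bar at the geometric mean of the 2 arrays of each group, red for erstressin, blue for nostressin, grey for vehicle and open circles for erstressin without cytokines. DDIT3 was at a ratio of 18.0 under erstressin and 0.82 under nostressin at 6.5 h, NOS2 at 1.97 and 9.77, and IL6 at 18 h at 1.06 under erstressin and 15.0 under nostressin.

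Against nostressin at 6.5 h, the ER stress genes rose with erstressin by amounts close to those against vehicle. DNAJB9 was higher by 4.78 ± 0.16, DDIT3 by 4.45 ± 0.16, TRIB3 by 4.24 ± 0.21, HERPUD1 by 3.28 ± 0.11 and HSPA5 by 1.41 ± 0.09 (adjusted p = 3.2e-07). TXNIP, which binds thioredoxin, rose by 3.33 ± 0.10, and GADD45A, a growth arrest gene, by 3.84 ± 0.12. NOS2 fell by 2.31 on the log2 scale (SE 0.21, 95% CI -2.76 to -1.86, adjusted p = 6.4e-06). CCL8 changed by -4.49 ± 0.18, TNF by -2.43 ± 0.20, IL1B by -2.41 ± 0.18, IDO1 by -2.22 ± 0.14 and CXCL10 by -0.74 ± 0.10. IL6 differed by -0.80 (adjusted p = 0.0077), but its call was lost without erstressin replicate 1 (-0.66) or nostressin replicate 2 (-0.74). ICAM1 differed by 0.88 (adjusted p = 0.0095), with its call lost without erstressin replicate 1 (0.54), nostressin replicate 1 (0.86) or nostressin replicate 2 (0.90). HMOX1 differed by 0.02 (95% CI -0.20 to 0.24), PTGS2 by -0.07 (95% CI -0.23 to 0.09) and IRF1 by 0.20 (95% CI -0.08 to 0.48), and none of these passed.

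ER chaperones had 18 of 23 members higher with erstressin than with nostressin at 6.5 h and 1 lower (20 and 1 adjusted over the list alone, median 0.85, adjusted p = 1.0e-21), with SDF2L1 at 3.18 ± 0.12. The integrated stress response had 13 of 21 higher and 1 lower (15 and 1 adjusted over the list alone, median 1.15, adjusted p = 5.2e-15), and CEBPG rose by 2.72 ± 0.18. Amino acid genes had 14 of 19 higher and 1 lower (16 and 1 adjusted over the list alone, median 0.96, adjusted p = 8.7e-19), including SLC7A11 at 2.48 ± 0.12 and SLC1A4, a neutral amino acid transporter, at 2.12 ± 0.13. Aminoacyl-tRNA synthetases had 8 of 15 higher and 3 lower (9 and 3 adjusted over the list alone, adjusted p = 8.5e-05, adjusted p = 0.10 with an estimated correlation). ER translocation had 8 of 24 higher and 0 lower (10 and 0 adjusted over the list alone, adjusted p = 1.2e-05, adjusted p = 0.36 with an estimated correlation). Of 26 cytokines and chemokines 12 fell and 1 rose (13 and 3 adjusted over the list alone, adjusted p = 5.0e-05, adjusted p = 0.16 with an estimated correlation), and their median of -0.36 was -0.24 without erstressin replicate 2. The immediate early genes had 11 of 26 higher and 2 lower (12 and 3 adjusted over the list alone, adjusted p = 5.5e-05, adjusted p = 0.058 with an estimated correlation). NF-kB targets went both ways, with 10 of 25 higher and 6 lower (13 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.051). Lists with small shifts that passed were mitosis (median 0.14), ER-associated degradation (0.14), p53 targets (0.08) and cytosolic heat shock (-0.14). The calls for p53 targets and ER-associated degradation were lost without erstressin replicate 1. Those for mitosis and cytosolic heat shock were lost without erstressin replicate 2.

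Between the compounds at 6.5 h 1675 genes differed, 969 higher with erstressin and 706 lower. The count was 949 without erstressin replicate 2 (573 higher and 376 lower), 901 without nostressin replicate 1 (625 and 276) and 767 without nostressin replicate 2 (509 and 258). With only these 2 groups in the model 736 were higher and 383 lower.

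**Figure D2:**
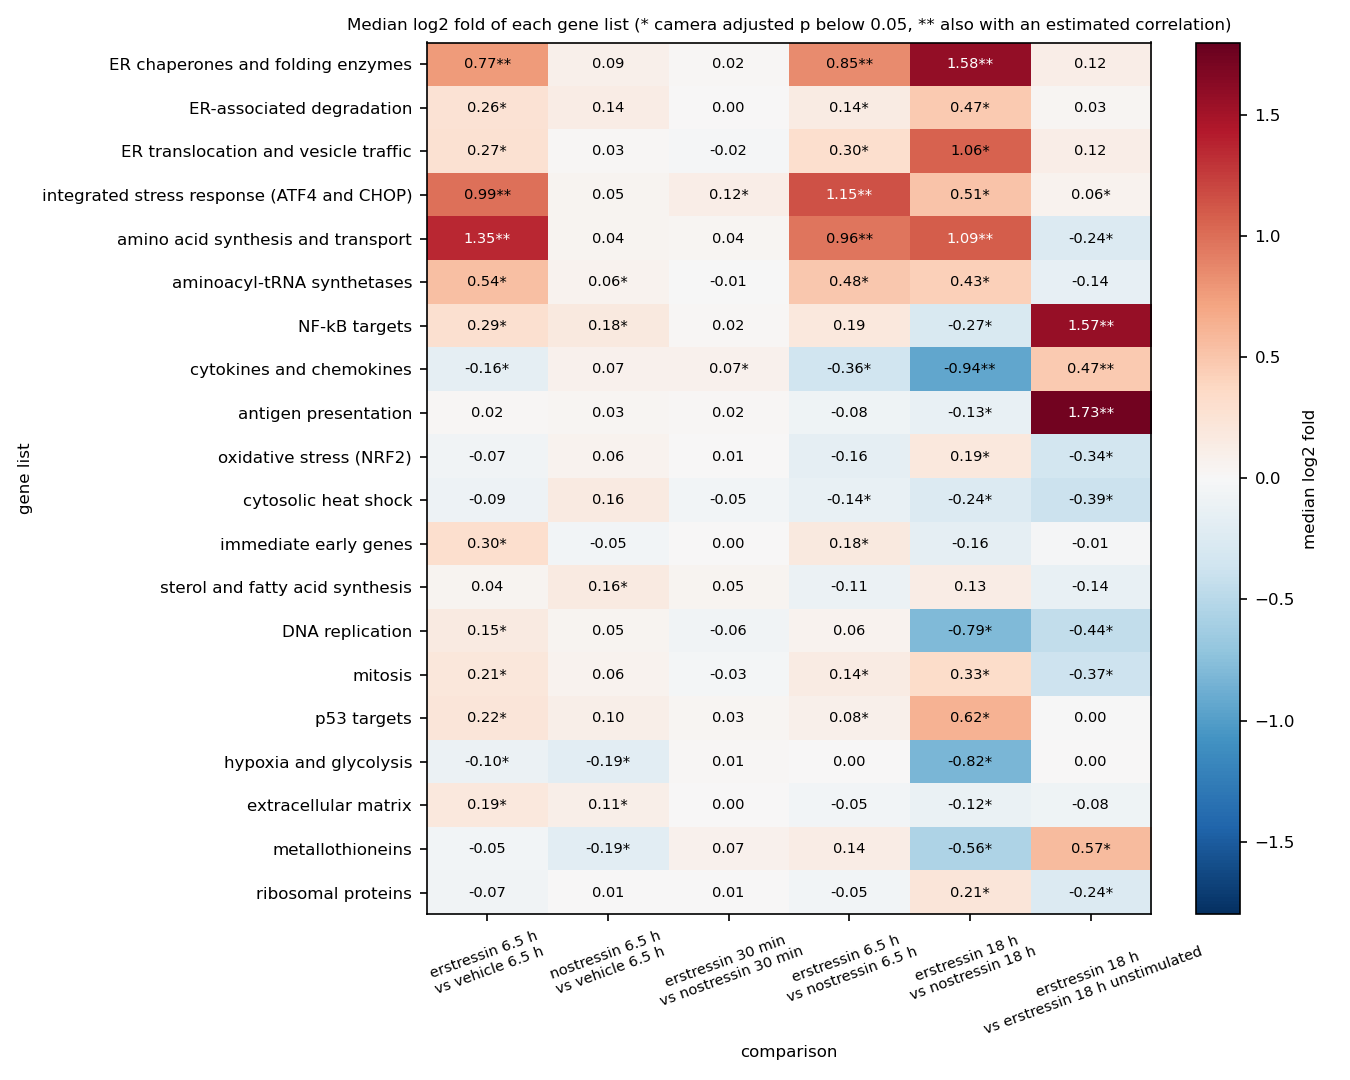
Median log2 fold of each of 20 gene lists (vertical) in the 6 main comparisons (horizontal), coloured from blue (lower) to red (higher), with stars for camera calls. ER chaperones had medians of 0.77, 0.85 and 1.58 under erstressin against vehicle at 6.5 h, nostressin at 6.5 h and nostressin at 18 h, and NF-kB targets a median of 1.57 with cytokines against without.

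At 18 h the ER stress genes were still higher with erstressin than with nostressin. DNAJB9 was higher by 4.26 ± 0.16, TRIB3 by 4.07 ± 0.21, DDIT3 by 3.42 ± 0.16, CRELD2 by 3.60 ± 0.11 and HSPA5 by 2.31 ± 0.09 (adjusted p = 1.0e-09). PLK2, a polo-like kinase, rose by 3.87 ± 0.13 and the GTPase regulator ARHGAP29 by 3.89 ± 0.15. Among cytokine transcripts CCL8 changed by -6.18 ± 0.18, CCL20 by -5.76 ± 0.29, IL1B by -5.63 ± 0.18, IL6 by -3.82 ± 0.18 and CXCL8 by -2.70 ± 0.11. ICAM1 differed by 0.82 (adjusted p = 0.0089), a call lost without erstressin replicate 1 (0.69), without nostressin replicate 2 (0.60) or with the first-numbered 18 h arrays alone (0.72). With the probe set of highest SD or highest mean it was 1.42 (adjusted p = 0.0020 and 0.0022). NOS2 differed by -0.61 (SE 0.21, 95% CI -1.06 to -0.16) and did not pass (adjusted p = 0.054). It passed with no intensity trend (adjusted p = 0.048), with only these 2 groups in the model (adjusted p = 0.043) or over the upper part of genes by SD (adjusted p = 0.026).

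ER chaperones had 21 of 23 members higher with erstressin at 18 h and 1 lower (22 and 1 adjusted over the list alone, median 1.58, adjusted p = 1.1e-24). ER translocation and vesicle traffic had 22 of 24 higher and 0 lower, also 22 adjusted over the list alone, with a median of 1.06 (adjusted p = 8.6e-19, adjusted p = 0.060 with an estimated correlation). SSR3, a subunit of the translocon-associated complex, rose by 2.06 ± 0.19 and SEC23B, a coat protein of transport vesicles, by 1.73 on the log2 scale. Amino acid genes had 15 of 19 higher and 1 lower (16 and 1 adjusted over the list alone, median 1.09, adjusted p = 5.9e-15), with SLC7A11 at 3.76 ± 0.12 and SLC3A2 at 2.19 ± 0.09. Aminoacyl-tRNA synthetases had 10 of 15 higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 3.0e-06, adjusted p = 0.060 with an estimated correlation), led by IARS1 at 1.87 ± 0.09. The integrated stress response had 13 of 21 higher and 4 lower (14 and 4 adjusted over the list alone, adjusted p = 3.0e-06, adjusted p = 0.060 with an estimated correlation). ER-associated degradation had 10 of 17 higher and 1 lower (10 and 2 adjusted over the list alone, adjusted p = 2.9e-05, adjusted p = 0.32 with an estimated correlation), and its median of 0.47 was 0.31 without erstressin 18 h replicate 1. SEL1L, an adaptor of that pathway, rose by 1.91 ± 0.12.

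Of 26 cytokines and chemokines 16 fell at 18 h and 1 rose (16 and 2 adjusted over the list alone, median -0.94, adjusted p = 1.6e-12). NF-kB targets had 10 of 25 lower and 4 higher (13 and 5 adjusted over the list alone, adjusted p = 0.0032, adjusted p = 0.36 with an estimated correlation), and their median of -0.27 was -0.17 without nostressin 18 h replicate 1. IER3, an early response gene, fell by 1.81 (SE 0.09). Antigen presentation had 5 of 24 lower and 1 higher (6 and 2 adjusted over the list alone, adjusted p = 0.049, adjusted p = 0.52 with an estimated correlation). That call was lost without erstressin 18 h replicate 2 (adjusted p = 0.18) or nostressin 18 h replicate 1 (adjusted p = 0.15), and the median of -0.13 turned to 0.0053 after quantile normalization.

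Hypoxia and glycolysis genes fell in 19 of 23 cases at 18 h and 0 rose (19 and 1 adjusted over the list alone, median -0.82, adjusted p = 9.2e-15, adjusted p = 0.060 with an estimated correlation). ADM changed by -3.85 ± 0.12, PFKFB3 by -2.87 ± 0.21 and BNIP3, a mitochondrial protein of the BCL2 family, by -1.69 ± 0.15. DNA replication genes had 20 of 28 lower and 1 higher (21 and 1 adjusted over the list alone, median -0.79, adjusted p = 3.8e-12, adjusted p = 0.063 with an estimated correlation). The helicase subunit MCM6 fell by 1.84 (SE 0.15) and GINS2 by 1.93 (SE 0.14), while the licensing factor CDC6 rose by 1.87 ± 0.18. Mitosis genes had 11 of 28 higher and 0 lower (15 and 1 adjusted over the list alone, adjusted p = 2.9e-05, adjusted p = 0.45 with an estimated correlation), among them CENPA at 1.51 ± 0.19 and TOP2A at 1.36 ± 0.16. The p53 targets had 9 of 17 higher and 1 lower (10 and 2 adjusted over the list alone, adjusted p = 1.4e-04, adjusted p = 0.31 with an estimated correlation), including DDB2 at 1.28 ± 0.11 and CDKN1A, the cell-cycle inhibitor p21, at 0.79 ± 0.12. Of 8 metallothioneins 6 fell and 0 rose, the same counts adjusted over the list alone (adjusted p = 3.5e-04, adjusted p = 0.35 with an estimated correlation), with MT1X at -1.23 ± 0.14.

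Smaller shifts between the compounds at 18 h concerned the remaining lists. Oxidative stress genes had 4 of 17 higher and 1 lower (5 and 2 adjusted over the list alone, adjusted p = 0.0089, adjusted p = 0.36 with an estimated correlation), with TXNRD1, thioredoxin reductase, at 1.46 ± 0.09. Ribosomal protein genes had 8 of 19 higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.0026, adjusted p = 0.52 with an estimated correlation). Cytosolic heat shock genes had 5 of 18 lower and 2 higher (6 and 2 adjusted over the list alone, adjusted p = 0.023, adjusted p = 0.52 with an estimated correlation), a call lost without erstressin 18 h replicate 2 (adjusted p = 0.077) or nostressin 18 h replicate 1 (adjusted p = 0.077). Extracellular matrix genes had 7 of 29 lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.015, adjusted p = 0.52 with an estimated correlation). Their median of -0.12 was -0.25 without erstressin 18 h replicate 1, and the call was lost without erstressin 18 h replicate 2 (-0.05, adjusted p = 0.11). Sterol and fatty acid genes had 9 of 20 higher and 3 lower (9 and 3 adjusted over the list alone, adjusted p = 0.10) and immediate early genes 4 of 26 higher and 9 lower (5 and 10 adjusted over the list alone, adjusted p = 0.052). INSIG1, a sterol sensor of the ER, fell by 1.74 on the log2 scale.

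Of all genes 2467 differed between the compounds at 18 h, with 1378 higher and 1089 lower under erstressin, and 1351 with only these 2 groups in the model (745 higher and 606 lower). Which direction held more genes depended on single arrays, with 930 higher and 1133 lower without erstressin replicate 1, and 880 and 1036 without nostressin replicate 2. Genes higher in both comparisons of the compounds, at 6.5 h and 18 h, numbered 465 (112 if the calls were independent), and 277 were lower in both (64.3 if independent), while 86 passed in opposite directions.

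**Figure D3:**
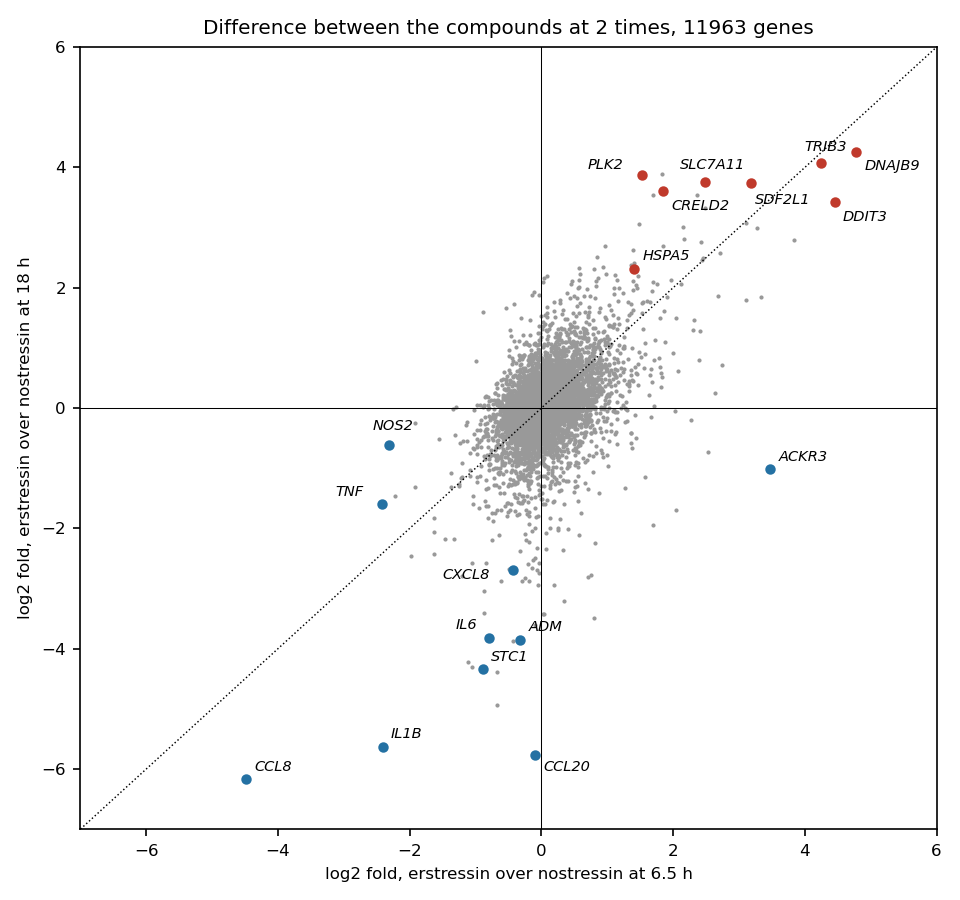
Log2 fold of erstressin over nostressin for 11963 genes at 6.5 h (horizontal) and 18 h (vertical), 1 point per gene, with a dotted line of equal change and coloured points for named genes picked as examples. DNAJB9 lay near that line at 4.78 and 4.26, while CCL20 moved from -0.09 to -5.76 and NOS2 from -2.31 to -0.61.

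Within erstressin at 18 h, cultures with the cytokine cocktail were compared with cultures without it. IDO1 was higher by 7.98 ± 0.14, the chemokine CXCL2 by 6.31 ± 0.20, CCL2 by 6.10 ± 0.09 and CXCL8 by 5.04 ± 0.11. CXCL10, GBP1 and CCL5 lay at the floor in both unstimulated arrays and VCAM1 in 1 of them, so that CXCL10 was at least 105-fold higher, VCAM1 at least 116-fold, and CCL5 at least 145-fold and 142-fold by its probe sets. NOS2 differed by 0.27 (95% CI -0.18 to 0.72, adjusted p = 0.42). Of the ER stress genes in the panel ATF3 rose by 1.62 ± 0.10, and the others did not pass, with HSPA5 at -0.14 (95% CI -0.33 to 0.06), DDIT3 at -0.13 (95% CI -0.47 to 0.21) and DNAJB9 at 0.25 (95% CI -0.10 to 0.60). Quantile normalization, which gives all arrays the same distribution, gave 5.29 for IDO1, 3.70 for CXCL2, 3.59 for CCL2 and 3.10 for CXCL8. It widened other folds, such as that of INSIG1 from -0.49 to -1.11.

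IRF1, a transcription factor of the interferon response, rose by 3.65 ± 0.13 with cytokines. Antigen presentation genes had 23 of 24 higher and 0 lower (24 adjusted over the list alone, median 1.73, adjusted p = 2.7e-35), led by CD74 at 6.01 ± 0.32 and HLA-DRA at 4.21 ± 0.18. NF-kB targets had 19 of 25 higher and 0 lower, also 19 adjusted over the list alone (median 1.57, adjusted p = 1.2e-25), with NFKBIA at 3.54 ± 0.18. Cytokines and chemokines had 13 of 26 higher and 0 lower, also 13 adjusted over the list alone (median 0.47, adjusted p = 5.9e-16). Metallothioneins rose in 6 of 8 cases (7 adjusted over the list alone, median 0.57, adjusted p = 2.5e-05, adjusted p = 0.25 with an estimated correlation), with MT2A at 0.85 and MT1X at 0.79.

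DNA replication genes fell in 17 of 28 cases with cytokines and 0 rose (18 adjusted over the list alone, median -0.44, adjusted p = 2.2e-06, adjusted p = 0.21 with an estimated correlation), and GINS2 fell by 1.42 (SE 0.14). Mitosis genes fell in 15 of 28 cases and 0 rose (17 adjusted over the list alone, adjusted p = 2.8e-05, adjusted p = 0.45 with an estimated correlation). Cytosolic heat shock genes had 9 of 18 lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 0.0037, adjusted p = 0.38 with an estimated correlation), with HSPB8 at -1.45 ± 0.13. Oxidative stress genes had 9 of 17 lower and 1 higher (9 and 3 adjusted over the list alone, adjusted p = 0.0065, adjusted p = 0.36 with an estimated correlation), including GCLC at -1.45 ± 0.21 and NQO1 at -0.71 ± 0.09. Ribosomal protein genes had 7 of 19 lower and 0 higher (9 adjusted over the list alone, adjusted p = 7.1e-04, adjusted p = 0.51 with an estimated correlation). ER chaperones had 1 of 23 higher and 0 lower, also 1 adjusted over the list alone, and did not pass (median 0.12, adjusted p = 0.087). The integrated stress response had 4 of 21 higher and 0 lower, also 4 adjusted over the list alone (adjusted p = 0.032, adjusted p = 0.36 with an estimated correlation), a call lost without erstressin 18 h replicate 1 (adjusted p = 0.11), after quantile normalization (adjusted p = 0.19) and with the probe set of highest SD (adjusted p = 0.089). The amino acid list went the other way and passed as lower at the preset correlation (median -0.24). Its median was -0.12 without erstressin 18 h replicate 2. Without unstimulated replicate 2 the median was -0.22 and the call was lost. Outside the lists the largest falls were in CCN2, a matricellular growth factor, at -4.53 ± 0.26, HAPLN1 at -3.92 ± 0.15 and ID1, an inhibitor of differentiation, at -3.06 ± 0.11.

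With cytokines 2430 genes differed from unstimulated erstressin cultures, 750 higher and 1680 lower. The count was 1361 without erstressin 18 h replicate 2 (609 higher and 752 lower), 1355 without unstimulated replicate 1 (500 and 855), 1521 without unstimulated replicate 2 (498 and 1023), and 1512 with the first-numbered 18 h arrays of both compounds alone (647 and 865). Among these counts the excess of falls was smallest without erstressin 18 h replicate 2, and it also shrank without either unstimulated array. Its size thus depends on single arrays.

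Changes over time were tested within each compound. From 30 min to 6.5 h NOS2 rose by 3.63 ± 0.21 under nostressin and by 1.23 ± 0.21 under erstressin, and from 6.5 h to 18 h it changed by -2.68 ± 0.21 under nostressin and by -0.98 ± 0.21 under erstressin. The last of these was -0.58 without erstressin 6.5 h replicate 1, and its call was lost with only those 2 groups in the model. DDIT3 rose by 4.27 from 30 min to 6.5 h under erstressin and changed by -0.01 under nostressin (adjusted p = 0.97). ADM rose by 4.99 ± 0.12 and IL6 by 2.92 ± 0.18 from 6.5 h to 18 h under nostressin, and the latter value was 1.90 after quantile normalization. Under erstressin CCL20 changed by -5.62 and the scavenging chemokine receptor ACKR3 by -4.59 between 6.5 h and 18 h.

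Between 30 min and 6.5 h 2996 genes changed under erstressin and 2338 under nostressin, and between 6.5 h and 18 h 2648 and 2680. The counts were 1722 for the later interval of erstressin without its 18 h replicate 2, 1010 with only its 2 groups in the model, and 1783 for that of nostressin without its 6.5 h replicate 1. For the earlier interval of nostressin they were 1363 without its 30 min replicate 1 and 1396 without its 6.5 h replicate 2.

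The comparisons of each compound with vehicle at 6.5 h used the same vehicle arrays. Genes higher with both compounds numbered 25 (4.74 if the calls were independent), genes lower with both 8 (0.607 if independent), and 1 gene, WDR6 (chosen after its values were seen), passed in opposite directions at -0.55 with erstressin and 0.60 with nostressin. The folds of the compounds correlated across genes at 0.349. In 100 simulations of unchanged groups with a drawn shared vehicle and independent genes, the correlation was 0.50 (SD 0.00777). The same sign was seen for 64.9% of genes against 66.7%. A shared control of equal group size itself sets the simulated correlation, and an effect of erstressin alone would lower the observed one. These 2 measures therefore do not show how alike the compounds are. The covariance of the folds was 0.0246 against 0.00835 in the simulations, a difference of 0.0163. The correlation was 0.200 without erstressin replicate 1. A split of the 2 vehicle arrays would leave 1 for each compound, so the controls were not split, and part of the shared calls may come from them.

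Cell type markers gave 1 call among 24 tests of 4 lists, for the markers of the line's own lineage. Markers of glia or mesenchymal-type glioma were lower with erstressin than with nostressin at 18 h, with 5 of 10 lower and 0 higher (6 and 1 adjusted over the list alone, median -0.26, adjusted p = 0.0019, adjusted p = 0.080 with an estimated correlation). Among them NES, an intermediate filament of neural progenitors, fell by 2.05 (SE 0.10) and CHI3L1 by 1.59 (SE 0.09), both chosen after their values were seen. In the same comparison leukocyte markers had 0 of 12 passing (median -0.11, adjusted p = 0.63), epithelial markers 0 of 7 (median 0.05, adjusted p = 0.73) and endothelial markers 2 of 5 lower (median -0.07, adjusted p = 0.55).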

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

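The tests for NOS2 below were chosen only after its result was seen. The results in this part were picked out because the change over time differed between erstressin and nostressin by the limma interaction test (differences given as erstressin minus nostressin, log2 ± SE, n = 2 arrays per group), and with groups of 2 no single array could be judged as standing apart. Between 30 min and 6.5 h 772 genes differed in their change, with 527 higher and 245 lower under erstressin, and between 6.5 h and 18 h 1325 genes did, with 630 higher and 695 lower. The earlier count was 399 and 436 without either 30 min array of erstressin, 1165 and 508 without its 6.5 h replicates 1 and 2, 462 without nostressin 30 min replicate 1, and 454 and 380 without the 6.5 h replicates 1 and 2 of nostressin. The later count was 823 without nostressin 6.5 h replicate 2 (376 higher and 447 lower). Without nostressin 6.5 h replicate 1 it held 394 higher and 533 lower, and more were higher than lower without erstressin 18 h replicate 2 (647 and 482), nostressin 18 h replicate 1 (643 and 490) or erstressin 6.5 h replicate 2 (561 and 554). Quantile normalization gave 1263 for the earlier interval (811 higher and 452 lower), and a model with only the compared groups gave 673 for the later (280 higher and 393 lower).

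From 30 min to 6.5 h the ER stress genes rose more under erstressin: DNAJB9 by 4.86 ± 0.23, TRIB3 by 4.32 ± 0.29, DDIT3 by 4.28 ± 0.22, HERPUD1 by 3.27 ± 0.15, ASNS by 1.83 ± 0.13, HSPA5 by 1.53 ± 0.13, ATF4 by 1.48 ± 0.15, XBP1 by 1.39 ± 0.20 and ATF3 by 1.23 ± 0.15. GADD45A, outside the panel, differed by 3.98 ± 0.17. Among inflammatory genes CCL8 differed by -4.44 ± 0.25, TNF by -2.56 ± 0.29, IL1B by -2.53 ± 0.26 and NOS2 by -2.40 ± 0.29 (adjusted p = 2.4e-04). Smaller differences in NFKBIA (-0.97 ± 0.25, adjusted p = 0.034), CXCL8 (-0.75 ± 0.16, adjusted p = 0.013) and CCL2 (-0.53 ± 0.13, adjusted p = 0.032) each lost their call without at least 4 of the 8 arrays taken in turn. Examples are NFKBIA without nostressin 30 min replicate 1 (-0.72, adjusted p = 0.15), CXCL8 without erstressin 6.5 h replicate 2 (-0.60, adjusted p = 0.059) and CCL2 without nostressin 30 min replicate 1 (-0.45, adjusted p = 0.19). For CXCL10 all 4 arrays at 30 min lie at the floor, so the fitted -0.74 only restates its difference at 6.5 h and no exact difference of changes can be given. The classes went both ways: of 26 cytokines and chemokines 8 differed downward and 1 upward, and of 25 NF-kB targets 3 downward and 6 upward. Of the 23 ER chaperones 13 differed upward and 0 downward over this interval, and of the 21 integrated stress response genes 12 and 0.

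From 6.5 h to 18 h the gap in NOS2 between the compounds narrowed by 1.70 ± 0.29 (adjusted p = 0.0019), as it changed by -2.68 under nostressin and by -0.98 under erstressin. HSPA5 changed by -0.68 under nostressin (-0.39 after quantile normalization) and did not pass under erstressin (0.22, adjusted p = 0.11). The change over this interval was thus higher under erstressin for HSPA5 (0.90 ± 0.13, adjusted p = 4.8e-04). It was also higher for DIRAS3 (2.48 ± 0.17), PLK2 (2.34 ± 0.18), PRSS23 (2.21 ± 0.13), ZMAT3 (2.15 ± 0.22) and CDKN1A (1.14 ± 0.17), and CDKN1A fell by 1.61 on the log2 scale under nostressin. It was lower for several transcription factors of the stress response, with ATF3 at -1.23 ± 0.15, DDIT3 at -1.03 ± 0.22, ATF4 at -0.90 ± 0.15 and XBP1 at -0.73 ± 0.20. The call for DDIT3 was lost without nostressin 6.5 h replicate 1 (-0.94, adjusted p = 0.067). That for XBP1 was lost without erstressin 18 h replicate 2 (-0.49), erstressin 6.5 h replicate 1 (-0.63), nostressin 18 h replicate 1 (-0.65) or nostressin 6.5 h replicate 2 (-0.62), and after quantile normalization (-0.55). CCL20 differed by -5.67 ± 0.42, ACKR3 by -4.49 ± 0.33, AMPD3 by -4.28 ± 0.23, SNX10 by -4.27 ± 0.23, IL6 by -3.01 ± 0.25 and CXCL8 by -2.26 ± 0.16. After quantile normalization IL6 was at -1.99 and CXCL8 at -1.30. Over this interval 12 of 23 ER chaperones differed upward and 2 downward, and of 21 integrated stress response genes 2 differed upward and 8 downward.

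The lower NOS2 under erstressin at 6.5 h could come from 1 odd array, from scaling, from a weaker response to the cytokines as a whole, or from an effect on fewer genes that include NOS2. Without either erstressin array in turn the difference was -1.91 or lower, and after quantile normalization it was -2.32, which speaks against the first and the second. The 100 genes highest in the vehicle cultures at 6.5 h over the 30 min arrays, a choice that used neither compound's 6.5 h arrays and left NOS2 out, stood at a median of 3.50 above 30 min. Between the compounds at 6.5 h they had a median difference of -0.156 (quartiles -0.45 and 0.25), with 16 higher and 29 lower. The line for a uniformly weaker response, a median below -1, was set after the result was seen. The median speaks against a uniform weakening of that size, but a smaller weakening is not excluded. CCL8, IL1B, TNF and IDO1 fell along with NOS2. At 18 h the same 100 genes had a median of -0.54 (quartiles -1.26 and -0.23), with 7 higher and 61 lower.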

How the results depend on the processing

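All tests in this part repeat reported results under another choice. The alternatives by SD, quantile normalization for lists, the first-numbered 18 h arrays alone and the crossed pairing were chosen only after the results were seen. Named genes kept direction and side of the threshold in 522 of 522 values when arrays were centred on their medians, 498 under quantile normalization (12 weaker, 8 stronger, 4 reversed), 519 with a robust variance prior, 521 without an intensity trend, 509 with the probe set of highest mean ratio, which is not that of highest signal (12 weaker, 1 reversed), 513 with that of highest SD, and 463 with only the groups compared in the model (56 weaker). With an array left out, 2077 values kept direction and side, 211 became weaker and 8 stronger. A lone remaining array was assumed to vary like the other groups. Of the 67 calls among 126 list tests, 13 held with an estimated correlation and 54 were lost. Of all 126 list tests, called or not, 112 kept direction and side of the threshold under fry, another list test of limma (9 weaker, 5 stronger), and 117 under quantile normalization (8 weaker, 1 reversed).

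Counts of changed genes moved over 1.5 times as follows. With only the compared groups in the model, the variance comes from fewer arrays and from those groups alone. The counts were then 1165 for erstressin against vehicle (1864 with all arrays) and 372 for nostressin against vehicle (57). They were 1351 for the compounds at 18 h (2467), 1010 for erstressin from 6.5 h to 18 h (2648) and 673 for the interaction of compound with the later interval (1325). The groups differed in spread. The SD of the log2 difference between replicates was 0.238 for erstressin, 0.140 for nostressin and 0.172 for vehicle at 6.5 h. At 18 h it was 0.243 for erstressin and 0.230 for nostressin. How far this moved the counts was not tested. Quantile normalization gave 1 gene for the compounds at 30 min (0), 378 for nostressin against vehicle and 1263 for the interaction with the earlier interval (772), and the cause was not tested. Testing all probe sets gave 90 for nostressin against vehicle. The first-numbered 18 h arrays alone, which leave fewer arrays, gave 1512 for stimulated against unstimulated erstressin (2430). From 6.5 h to 18 h under nostressin, 1083 genes rose and 1393 fell after quantile normalization (43.7% rising), against 894 and 1786 (33.4%).

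Values that turned in sign, the cause was not tested, were the antigen presentation list between the compounds at 18 h (0.0053 after quantile normalization), the hypoxia list between the compounds at 30 min (-0.088 without nostressin 30 min replicate 2, within a range of -0.088 to 0.077), and HLA-DRA between the compounds at 18 h (0.22 after quantile normalization). So did ASNS (0.70), DNAJB9 (0.55) and CXCL8 (-0.14) under nostressin from 6.5 h to 18 h after quantile normalization, and RPS6 between the compounds at 18 h (-0.033 with the probe set of highest mean).

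With an array left out in turn, counts ranged from 945 to 1569 for erstressin against vehicle, 1 to 29 for nostressin against vehicle, 0 to 0 at 30 min, 767 to 1879 for the compounds at 6.5 h, 1916 to 2298 at 18 h and 1355 to 2941 for stimulated against unstimulated erstressin. Over time they ranged from 2000 to 2712 and 1722 to 2866 under erstressin and 1363 to 2217 and 1783 to 2587 under nostressin, and for the interactions from 380 to 1165 and 823 to 1520. The correlation of the compounds against the shared vehicle ranged from 0.200 to 0.477.

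Replicate numbers are shared between groups but do not pair the arrays in every group: deviations of same-numbered arrays correlated between -0.360 and 0.603 over pairs of groups, 6 of 28 above 0.1. These 6 are all pairs among erstressin 18 h and the 3 nostressin groups (0.257 to 0.603), whose same-numbered arrays thus share structure. Of all arrays, 10 of 16 correlated best with their own number. Both arrays of a group mirror each other about its mean and give the same answer, so they do not count separately. No chance level was computed for this count. With the replicate number as a block the counts were 1884, 52, 0, 1667, 2466 and 2425 in the order of the report. Of the named values 521 kept direction and side of the threshold and 1 became weaker, CDC42SE1 for nostressin against vehicle (limma adjusted p = 0.051). Of the list tests 124 kept them, 1 became stronger and 1 weaker, antigen presentation between the compounds at 18 h (camera adjusted p = 0.053). A crossed block gave 34 for nostressin against vehicle, 0 at 30 min and 2933 for erstressin from 6.5 h to 18 h.

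Of the alternatives fixed before the data were examined, the stricter filter and the added constant of 16 gave no value because centred ratios hold no signal level, and running without a filter is what was done throughout. The mean of all probe sets, fixed as an alternative, became the way genes were summarized. Signal over background cannot be read from the ratios, so how far background shrinks a fold was not tested.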

Other observations

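All tests in this part were chosen only after the results were seen, except that the prediction for the second set of low-oxygen genes was written before its values were computed. The gene lists, the 20 panel genes and the comparisons were fixed before the data were examined. Some groups moved over time in the same direction under both compounds, by amounts that differed for part of their members. Of 24 antigen presentation genes 22 rose from 6.5 h to 18 h under erstressin and 21 under nostressin, with 0 falling, and HLA-DMA rose by 2.61 and 3.23 on the log2 scale. Of 20 sterol and fatty acid genes 11 fell under erstressin and 14 under nostressin, with 0 rising, and 5 of 20 differed between the compounds by the interaction test. The largest of these falls were in INSIG1 (-2.61 ± 0.12 under erstressin and -1.63 ± 0.12 under nostressin). Mitosis genes fell in 15 of 28 cases under erstressin (median -0.41) and 23 under nostressin (median -0.83), and KIF11, a spindle motor, changed by -1.80 and -1.77, while 3 of 28 differed by the interaction test. These examples were chosen after their values were seen.

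Other groups changed in different numbers under the compounds. DNA replication genes fell from 6.5 h to 18 h in 17 of 28 cases under erstressin and 0 rose, with RRM2, a subunit of ribonucleotide reductase, at -2.79 and RFC3 at -1.69. Under nostressin 7 rose and 5 fell, and the interaction test found 17 of 28 lower under erstressin and 0 higher, with MCM6 at -2.12. Metallothioneins rose in 7 of 8 cases under nostressin (median 0.66, MT1X 1.44 ± 0.14) and 0 of 8 passed under erstressin (median 0.02), and 5 of 8 differed downward by the interaction test. Extracellular matrix genes fell in 15 of 29 cases under erstressin, with TGFBI at -1.26 and the integrin ITGA5 at -0.99, and in 9 under nostressin, where 2 rose, and 5 of 29 differed by the interaction test. These examples, too, were chosen after their values were seen.

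Hypoxia and glycolysis genes were lower under erstressin than under nostressin at 18 h, which could come from wider arrays, from a fall under erstressin, or from a low-oxygen response in the nostressin cultures. The second-numbered 18 h arrays had a wider spread, but with the first-numbered arrays alone the list's median was still -0.72, and after quantile normalization of all arrays it was -0.66. Under erstressin the list did not fall from 6.5 h to 18 h (median 0.21, 6 rising and 2 falling of 23), while under nostressin 18 of 23 rose and 0 fell (median 1.05). A second set of 29 low-oxygen genes outside the list had a median rise of 0.455 under nostressin (quartiles 0.19 and 1.08, 18 rising and 0 falling, among them TMEM45A at 2.82 and INSIG2 at 2.41) and a median of -0.04 under erstressin, which is consistent with a broader low-oxygen response by this test. Vehicle at 18 h was not analysed here, so whether nostressin brings the rise about or erstressin prevents a rise with time stays open.

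Genes raised by cytokines were high in the vehicle cultures at 6.5 h, although the labels do not state a stimulus for them. The 100 genes most raised by cytokines at 18 h had a median difference of 0.033 between vehicle and nostressin at 6.5 h (quartiles -0.22 and 0.12), which is consistent with vehicle cultures that received the cocktail by this test. In single arrays the median of these genes lay 3.29 and 3.25 above the 30 min arrays on the log2 scale, so the pattern does not rest on 1 array, and in unstimulated erstressin cultures it lay 0.11 above them. NOS2 stood at a ratio of 6.79 under vehicle at 6.5 h, against 0.83 in unstimulated erstressin cultures at 18 h, and CXCL10 at 1.81 against the floor.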
